A study of Mus musculus with 8 samples.

How the data were processed

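The series profiled total RNA of pancreatic islets from wild type mice and from mice in which 1 gene had been knocked out. RNA was measured on 2 Affymetrix mouse oligonucleotide array types, MG-U74A and MG-U74B, with 2 replicates of each genotype on each type, which the labels call biological, 8 arrays in all.

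The deposited values are linear intensities, 1 per probe set, which the authors scaled so that the mean of each array without its highest and lowest 2% of probe sets was 250.2 on MG-U74A and 250.1 on MG-U74B. The software that made them is not given in the sources used here. Between 18.4% and 26.7% of the values of an array were below 0, as a difference between matched and mismatched probes can give. MG-U74A held 12488 probe sets and MG-U74B 12477. For arrays the number of replicates limits the precision.

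Each array was multiplied by 1 factor to bring that trimmed mean to the average of its array type, which changed no array by as much as 1%. Values below 0 were set to 0, and log2 was taken after adding 25.0, which is 10% of the common trimmed mean. On this scale the change of a gene with a low level in either genotype is smaller than the ratio of its intensities, and where a genotype is listed at or below 0 the log2 change depends on the constant added. Arrays of a genotype that are all at or below 0 have no spread after this step. Probe sets with a mean over the 4 arrays below 62.5 (25% of the common trimmed mean) and the 66 control probe sets of each array type were not tested, which left 7516 probe sets (60.2%) on MG-U74A and 7861 (63.0%) on MG-U74B.

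Knockout was compared with wild type on each array type separately, with lmFit and eBayes with a mean-variance trend from limma 3.58.1 in R 4.3.3. The test was two-sided, without a replicate block, with p adjusted by Benjamini-Hochberg within the array type and a threshold of 0.05. The estimated prior degrees of freedom were 2.11 on MG-U74A and 2.82 on MG-U74B. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so the p-values rest on limma's pooling of the spread across probe sets. They measure the spread between these arrays, which may be partly technical. Means below are means of 2 arrays with their standard deviation, and log2 changes are knockout minus wild type with their standard error.

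Probe sets were named from the array annotation, with symbols brought to current names through a table of the mouse assembly GRCm38.p6, used for names only. On MG-U74A 10855 probe sets had 1 symbol, of which 10839 have a current name, 396 had several and 1237 had none. On MG-U74B these numbers were 10603, 10572, 178 and 1696. The level of the targeted gene was not analysed here, and the genotypes rest on the labels.

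The tests, 30 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule took single-symbol genes past the threshold with both knockout arrays on the same side of both wild type arrays, by the probe set with the highest mean among those that met this. From these it named the 10 largest rises and 10 largest falls on MG-U74A and the 5 and 5 on MG-U74B, besides list members. Of the lists, 1 is counted in the totals and not reported here. The others covered islet transcription factors, insulin secretion, other islet hormones and peptides, acinar cells, the Reg family, duct cells, endothelial cells, fibroblast and stellate cells, macrophages and dendritic cells, lymphocytes, blood cells, fat cells, and nerve and Schwann cells. Further lists covered glycolysis, pyruvate use and the citric acid cycle, oxidative phosphorylation, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation, cell cycle, cell cycle inhibitors and apoptosis, endoplasmic reticulum stress, immediate early and heat shock genes, and interferon and antigen presentation. The last were liver-type secreted and metabolic genes, genes kept low in beta cells, ribosomal proteins, growth factor and insulin signalling, and brush border and solute transport.

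Lists with at least 5 tested genes on an array type were tested against the other genes with limma's camera at its preset inter-gene correlation of 0.01, with p adjusted over the lists of that array type. Camera with an estimated correlation and limma's fry were run beside it. With 4 arrays the correlation is estimated from few residuals. Camera then also takes its degrees of freedom from these residuals, so a list can fail whatever its correlation. Lists of lymph node vessels and follicles, clock genes and imprinted genes were added after values had been seen and were not tested as lists.

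The procedure was tested on simulated data with 2 arrays against 2, 200 changed probe sets and 10 simulations per array type. On MG-U74A it recovered 41.3% of changes of 1 log2 unit and 77.2% of changes of 2 units, with 5.12% false calls. On MG-U74B it recovered 1.60% and 24.5%, with 4.73% false calls. Lists of 20 genes shifted by 1 log2 unit passed in 10 of 10 simulations on both array types, and 0 of 500 unshifted lists passed camera on either type, with 6 and 7 at an unadjusted p below 0.05. In the data 52.9% and 17.5% of tested probe sets changed, far more than simulated, so these recovery rates do not measure the power there. Simulated noise was independent between genes, and unshifted lists held only unchanged genes. False list calls among correlated genes were therefore not tested.

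Alternatives covered the scaling, the constant added before log2, the filter, the variance trend, a replicate block, the threshold, adjustment over both array types, the correlation in camera, the probe sets per gene and each replicate left out in turn. After seeing the data, a further alternative left out immunoglobulin probe sets. Same-numbered arrays of the genotypes did not deviate together from their group means (correlation across probe sets 0.0241 and 0.0316), so the replicate numbers were not read as pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Control probe sets were used for quality measures only.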

Results

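Gene expression was measured in pancreatic islets of wild type and knockout mice, to ask which transcripts of the islet differ between them. The labels give each genotype 2 biological replicates, and whether these are separate RNA samples was not tested. Each replicate label had an array of type MG-U74A and an array of type MG-U74B. The median intensity of an array lay between 104 and 107 on MG-U74A and between 138 and 144 on MG-U74B. Wild type replicates were closest, with a Spearman correlation across probe sets of 0.979 on MG-U74A and 0.932 on MG-U74B. The knockout replicates correlated at 0.956 and 0.920. Arrays of different genotypes correlated at 0.865 to 0.868 on MG-U74A and at 0.824 to 0.842 on MG-U74B. These correlations are across probe sets, which are not independent replicates.

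The arrays of the genotypes also differed in their control probe sets. The ratio of the 3' to the 5' probe set of Gapdh, a measure of how complete the labelled RNA was, was 3.19 ± 0.0499 (SD, n = 2) in wild type and 0.943 ± 0.00849 in knockout on MG-U74A. On MG-U74B it was 3.10 ± 0.0382 and 0.907 ± 0.00964. A higher ratio means less complete RNA, so by this measure the wild type RNA was the less complete. The same ratio for actin was 1.46 ± 0.0157 in wild type and 1.14 ± 0.0269 in knockout on MG-U74A. The hybridisation control BioB averaged 183 ± 17.0 in wild type and 3820 ± 317 in knockout on MG-U74A, a 20.9-fold difference. The controls BioC, BioDn and Cre, added in the same way, were 0.706, 0.893 and 0.779 times their wild type level in knockout on that array type. No test was made of these values.

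**Figure D1:**
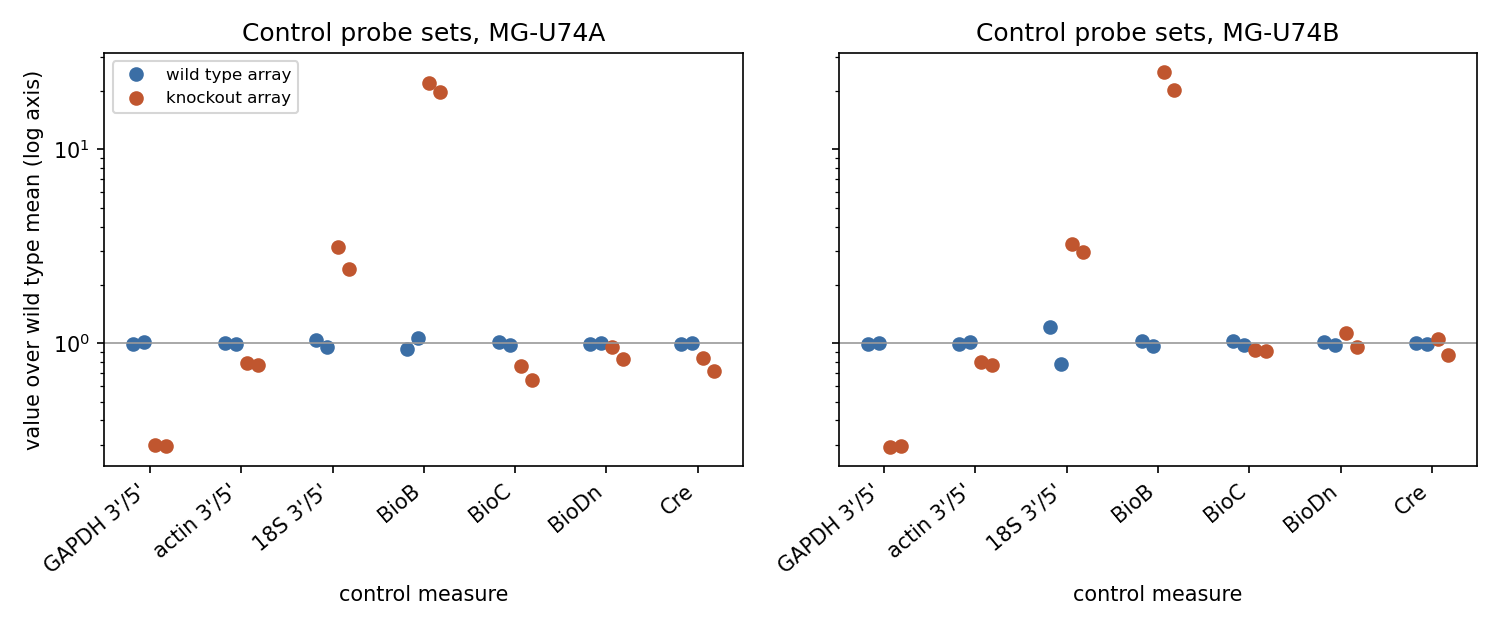
Control probe sets per array, wild type in blue and knockout in orange, on both array types. Shown are the 3' to 5' ratios of Gapdh, actin and 18S ribosomal RNA and the intensities of the hybridisation controls. Each value is divided by the wild type mean of its measure. Before this division the Gapdh ratio of every wild type array was above 3 and that of every knockout array was below 1.

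On MG-U74A the knockout islets had lower transcripts of beta cell function, of islet transcription factors and of acinar enzymes, and higher transcripts of lymphocytes, macrophages and fibroblasts. As groups they passed camera with its preset correlation and none passed with an estimated correlation (adjusted p between 0.247 and 0.325). The estimate was below the preset for lymphocytes (-0.077), acinar cells (-0.066) and macrophages and dendritic cells (-0.050), and above it for the other groups. A higher correlation was therefore not why those below it failed. The glucose transporter gene Slc2a2 fell by 3.93 ± 0.23 on the log2 scale, from 683 ± 30.0 to 22.3 ± 12.9 (SD, n = 2, adjusted p = 6.74e-04). Glycam1, a mucin of lymph node vessels, rose by 4.71 ± 0.06, from 64.4 ± 0.282 to 2322 ± 16.6 (adjusted p = 9.39e-05). Of the 7516 tested probe sets, 3974 (52.9%) changed, of which 1796 rose and 2178 fell. Among them 816 rose and 774 fell by at least 2-fold, and 108 rose and 44 fell by at least 8-fold. Both knockout arrays lay on the same side of both wild type arrays for 5944 probe sets (79.1%), where chance gives 33.3%. Without wild type replicate 1 more rose (1312) than fell (1142), and without wild type replicate 2 likewise (1298 and 1141), so the balance of rises and falls was not stable. Of 330 genes with at least 2 changed probe sets on this array type, 41 (12.4%) had probe sets that changed in opposite directions.

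The 10 largest rises on MG-U74A included genes of immune cells, among them Slfn2 (5.83 ± 0.11) and Cd79a, a chain of the B cell receptor (5.78 ± 0.11). Both were listed below 0 in wild type and reached 1395 ± 53.3 and 1348 ± 11.4 in knockout (adjusted p = 1.0e-04 for each). Since values below 0 were set to 0, the wild type pair has no spread for these genes, and the standard error and p rest on the knockout pair and limma's pooling. The immunoglobulin genes Ighv1-54, Igkv9-120 and Igkv14-111 rose by 4.81 ± 0.08, 4.75 ± 0.26 and 4.64 ± 0.06, where 2 other tested probe sets of Igkv9-120 did not pass the threshold. Tff3, a trefoil peptide of mucous epithelium, rose by 5.75 ± 0.49 from 13.3 ± 38.7 to 2159 ± 82.4 (adjusted p = 0.00171). The smooth muscle actin gene Acta2, listed below 0 in wild type, rose by 4.70 ± 0.21, and the kinase gene Pim1 rose by 4.65 ± 0.41. Sidt2, also listed below 0 in wild type, rose by 5.03 ± 0.15 on its brightest probe set, while its other tested probe set changed in the opposite direction.

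The 10 largest falls on MG-U74A included metabolic and secreted products besides Slc2a2. Stard10, a lipid transfer protein gene, fell by 5.58 ± 0.12, from 1173 ± 64.7 to a level listed below 0 (adjusted p = 1.08e-04). Rnase4, a secreted ribonuclease, fell by 4.35 ± 0.04, from 4446 ± 42.0 to 194 ± 2.54 (adjusted p = 8.54e-05). The thyroid hormone deiodinase gene Dio1 fell by 4.54 ± 0.22 from 641 ± 113 to 1.50 ± 8.06. Clps, pancreatic colipase (-4.58 ± 0.52), Wnt4 (-4.14 ± 0.17), Gata1 (-4.01 ± 0.17) and Fbp1, a gluconeogenic phosphatase (-3.94 ± 0.17), fell. Wnt4, Gata1 and Fbp1 were listed below 0 on both knockout arrays and Clps on 1 of them. The histone gene H1f2 fell by 4.73 ± 1.02 (adjusted p = 0.0217), a call that ended without wild type replicate 1 (adjusted p = 0.0742) or without wild type replicate 2 (adjusted p = 0.0740). Rps29 fell by 4.12 ± 0.17 on 1 probe set, to a level listed below 0, and its other tested probe set, with the higher mean, did not pass the threshold.

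**Figure D2:**
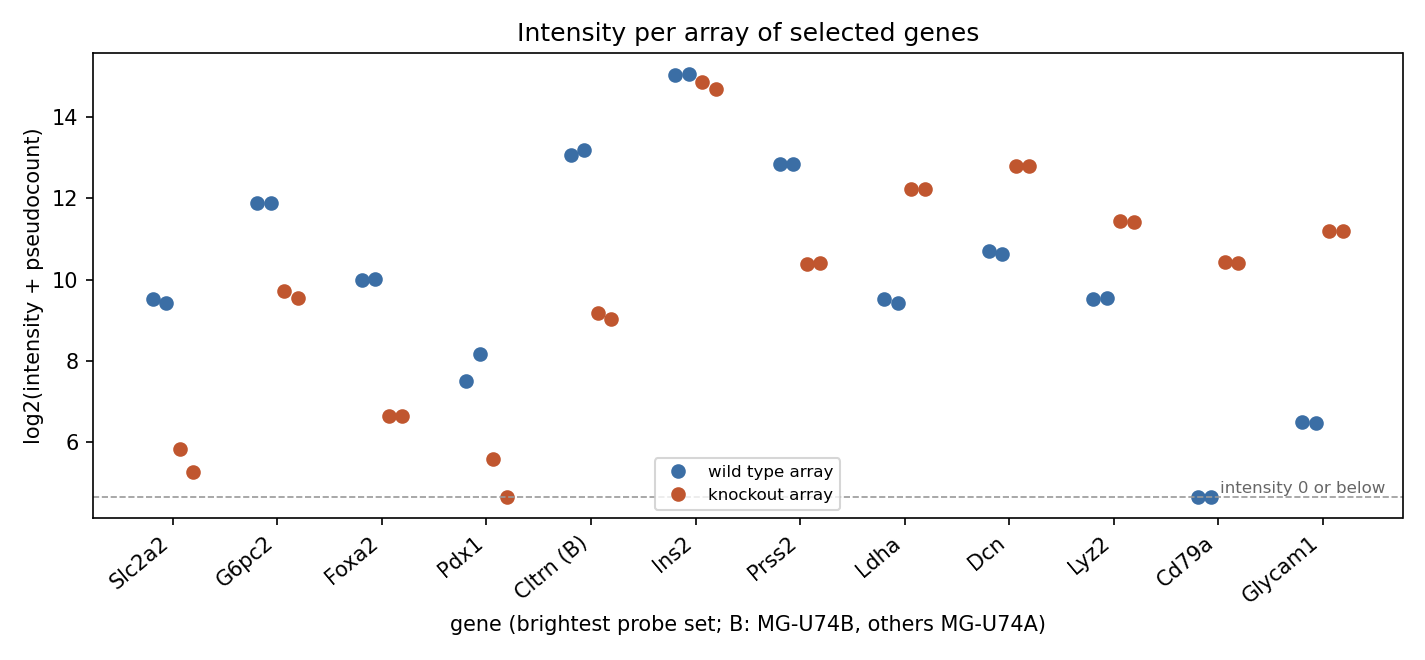
Intensity of selected genes on each array as log2 of the intensity plus the constant added, wild type in blue and knockout in orange, with the dashed line at intensities of 0 or below. Slc2a2, Foxa2 and Cltrn were lower in both knockout arrays, Ins2 lay near the top of the range, and Dcn, Cd79a and Glycam1 were higher in both knockout arrays.

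Of 22 tested genes of insulin secretion, 19 fell and 0 rose, with a median log2 change of -1.56, and 19 fell adjusted over the list alone. The list was lower than the other genes by camera (adjusted p = 1.16e-07), with adjusted p = 0.302 with an estimated correlation. The granule protein genes Chga (-2.46 ± 0.06) and Scg3 (-2.95 ± 0.05) fell, Chga from 6087 ± 64.1 to 1085 ± 78.1. G6pc2, the islet glucose-6-phosphatase, fell by 2.24 ± 0.07 from 3751 ± 6.47 to 773 ± 67.6, and the potassium channel subunit gene Abcc8 fell by 2.45 ± 0.14. The insulin gene Ins2 fell by 0.27 ± 0.06 (adjusted p = 0.0252) at intensities near the top of the range. Kcnj11, at -1.33 ± 0.55, Ptprn2, at -0.51 ± 0.42, and Syt7, at 0.24 ± 0.19, did not pass the threshold. These falls stood beside a lower Gapdh 3' to 5' ratio, a sign of more complete RNA, and higher lymphocyte and fibroblast transcripts in the same knockout arrays.

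Of 14 tested islet transcription factors, 9 fell and 0 rose on MG-U74A, with a median of -2.09. Adjusted over the list alone, 9 fell and 1 rose. The list was lower by camera (adjusted p = 0.00397), with adjusted p = 0.325 with an estimated correlation. Foxa2 fell by 3.36 ± 0.08 from 1001 ± 18.6 to 74.5 ± 0.493. Nkx2-2 (-2.86 ± 0.05), Neurod1 (-2.53 ± 0.07) and Pax6 (-2.40 ± 0.07) fell as well. Pdx1, needed for pancreas formation and insulin gene expression, fell by 2.72 ± 0.45 from 209 ± 76.9 to 8.50 ± 20.6 (adjusted p = 0.0101). It was listed below 0 on 1 knockout array, so the size of its fall depends on the constant added. Sox4, Gata6, Pax4, Nr5a2 and Gata4 did not pass the threshold. The same arrays differ in the Gapdh ratio and in transcripts of other cell types. The 13 other islet hormones and peptides went both ways, with 6 that fell and 3 that rose, the same counts adjusted over the list alone. Glucagon (Gcg, -0.88 ± 0.07), somatostatin (Sst, -0.84 ± 0.04) and pancreatic polypeptide (Ppy, -0.39 ± 0.06) fell, while the neuropeptide genes Vip and Penk rose by 1.00 ± 0.19 and 0.86 ± 0.16. Gcg, Sst and Ppy had high wild type means of 17386, 18923 and 24100. Whether the arrays show differences in full at such intensities was not tested. That list did not pass camera (adjusted p = 0.841), and its median of 0.05 and mean of -0.11 differ in sign.

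Acinar cell genes fell on MG-U74A, 14 of 16 tested, with a median of -2.56. 1 member, Dmbt1, rose by 0.61 ± 0.07, and the counts were the same adjusted over the list alone. Camera gave adjusted p = 3.18e-05, with adjusted p = 0.247 with an estimated correlation. Amy1 (amylase) fell by 3.79 ± 0.11 from 1264 ± 61.8 to 68.0 ± 9.97, and Cela1 (elastase, -3.22 ± 0.17) and Prss2 (trypsinogen, -2.45 ± 0.03) fell too. Of 5 tested Reg family genes 3 fell, the same number adjusted over the list alone, among them Reg2 (-2.62 ± 0.13) and Reg1 (-1.95 ± 0.07), and the list did not pass camera (adjusted p = 0.0972). Duct cell genes went both ways, with 8 that rose and 7 that fell of 17 (adjusted p = 0.640). Tff3 and Krt20 (1.79 ± 0.11) rose, while Prom1 (-2.31 ± 0.05) and Krt7 (-1.75 ± 0.04) fell. These changes stood beside the lower Gapdh 3' to 5' ratio and higher immune and fibroblast transcripts in the same knockout arrays.

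Immune cell transcripts were higher in knockout islets on MG-U74A, beside the Gapdh ratio that was lower on the same arrays. Of 13 tested lymphocyte genes, 11 rose and 0 fell, the same adjusted over the list alone, with a median of 2.07. Camera gave adjusted p = 3.71e-07, and adjusted p = 0.247 with an estimated correlation. Ighm (immunoglobulin M heavy chain) rose by 2.37 ± 0.05 from 2343 ± 26.6 to 12187 ± 693, Cd52 by 2.15 ± 0.03, Ccr7 (a homing receptor) by 2.27 ± 0.08 and the T cell gene Cd3d by 2.77 ± 0.38, and Zap70 and Cd4 did not pass the threshold. Of 20 macrophage and dendritic cell genes 19 rose and 0 fell, also adjusted over the list alone, with a median of 1.45 (adjusted p = 9.90e-09, and adjusted p = 0.247 with an estimated correlation). H2-Aa (an antigen-presenting molecule) rose by 2.77 ± 0.05, Ptprc (CD45) by 2.80 ± 0.15, C1qb (complement) by 2.69 ± 0.20 and Lyz2 (lysozyme) by 1.90 ± 0.04. Of 23 interferon and antigen presentation genes 17 rose and 0 fell, the same adjusted over the list alone, with a median of 1.04 (adjusted p = 1.16e-07, and adjusted p = 0.297 with an estimated correlation). Psmb9, Gbp2 and Igtp, all induced by interferon, rose by 2.98 ± 0.14, 2.69 ± 0.04 and 2.57 ± 0.06. On MG-U74B 3 members of that list were tested, too few for camera. Bst2 rose by 1.78 ± 0.16, Oasl2 fell by 0.93 ± 0.20 and Tap1 did not pass the threshold.

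Genes of fibroblast and stellate cells rose as well, 22 of 27 with 2 that fell, and 23 and 2 adjusted over the list alone. Their median was 1.17 (adjusted p = 9.90e-09, and adjusted p = 0.247 with an estimated correlation). The matrix genes Dcn and Col3a1 rose by 2.12 ± 0.04 and 1.92 ± 0.09, Dcn from 1602 ± 58.5 to 7062 ± 42.4, and Thy1 rose by 2.70 ± 0.18. The 2 that fell were Col1a2 (-0.34 ± 0.05), on a probe set opposed by another of the same gene, and Fbln1 (-0.45 ± 0.08). Endothelial genes rose in 9 of 14 cases and fell in 1, Emcn (-0.65 ± 0.10), with 9 and 2 adjusted over the list alone and a median of 0.51 (adjusted p = 0.0144, and adjusted p = 0.302 with an estimated correlation). Icam2 rose by 1.63 ± 0.20 and Cd34 by 1.26 ± 0.21. Of 5 tested blood cell genes 4 rose and 0 fell, also adjusted over the list alone, with a median of 2.16 (adjusted p = 0.00397, and adjusted p = 0.302 with an estimated correlation). They were the neutrophil genes S100a8 (2.82 ± 0.09) and S100a9 (2.84 ± 0.41) and the globin genes Hbb-b2 (2.16 ± 0.20) and Hba-a1 (1.03 ± 0.08). Fat cell genes split 2 to 2 of 6 (adjusted p = 0.832), where Lpl fell by 1.57 ± 0.05 and Scd1 rose by 1.04 ± 0.10. Nerve and Schwann cell genes had 1 rise and 3 falls of 6 (adjusted p = 0.640), where Prnp fell by 1.10 ± 0.03 and Pmp22 rose by 0.94 ± 0.08. The same knockout arrays had the lower Gapdh 3' to 5' ratio.

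**Figure D3:**
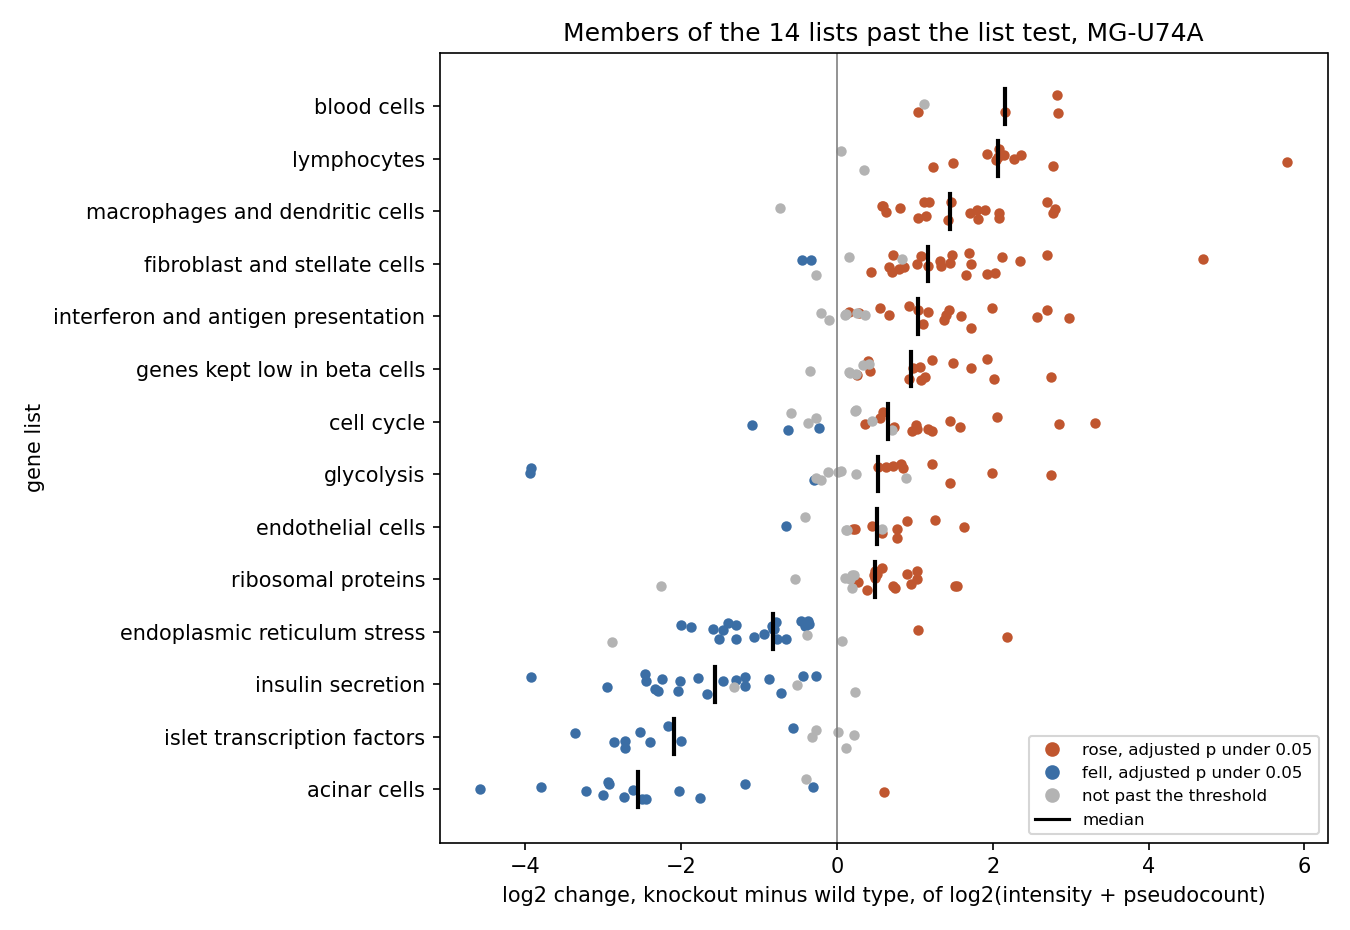
The log2 change of each tested member of the 14 gene lists that passed camera at its preset correlation on MG-U74A, knockout minus wild type. Members are in orange where they rose, blue where they fell and grey where they did not pass the threshold, with the list median as a black line. The 16 lists that did not pass are not shown. The medians of insulin secretion (-1.56), islet transcription factors (-2.09) and acinar cells (-2.56) lie below 0 and those of lymphocytes (2.07) and macrophages and dendritic cells (1.45) above it.

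Genes described as kept low in normal beta cells were higher in knockout islets. On MG-U74A 14 of 20 rose and 0 fell, the same adjusted over the list alone, with a median of 0.95 (adjusted p = 2.60e-06, and adjusted p = 0.247 with an estimated correlation). Ldha (lactate dehydrogenase) rose by 2.75 ± 0.05 from 685 ± 31.2 to 4753 ± 7.17, Cxcl12 by 2.01 ± 0.08, Oat by 1.93 ± 0.13 and the hexokinase gene Hk1 by 1.22 ± 0.05. On MG-U74B Cxcl12, at 0.68 ± 0.21, did not pass the threshold (adjusted p = 0.0925). Other cell types express several genes of this list, and the lists of lymphocytes, macrophages and dendritic cells, and fibroblast and stellate cells rose on the same arrays, while that of acinar cells fell. The knockout arrays of MG-U74A also had the lower Gapdh 3' to 5' ratio, beside this list and the next. In glycolysis 9 of 19 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.53 (adjusted p = 0.0356, and adjusted p = 0.303 with an estimated correlation). Pkm and Tpi1 rose by 1.99 ± 0.08 and 1.45 ± 0.03, and the 3 that fell were Slc2a2, Fbp1 and Pgam1 (-0.30 ± 0.08), of which Slc2a2 is a transporter and Fbp1 works in the reverse direction. The glycolysis call ended with quantile normalization (adjusted p = 0.0543), with no filter (0.0670), with no variance trend (0.0628) and without knockout replicate 2 (0.0787).

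Mitochondrial and lipid metabolism lists did not pass camera on MG-U74A. Oxidative phosphorylation had 16 rises and 12 falls of 47 genes (adjusted p = 0.640), with a median of -0.05 and a mean of 0.04 that differ in sign. Pyruvate use and the citric acid cycle had 5 rises and 10 falls of 25 (adjusted p = 0.675), where Idh2 (-1.64 ± 0.09) and Fh1 (-1.04 ± 0.04) fell. Cholesterol synthesis and uptake had 1 rise and 5 falls of 14 (adjusted p = 0.686), where Msmo1 fell by 1.45 ± 0.18. Fatty acid synthesis had 2 rises and 6 falls of 11 (adjusted p = 0.141), and Acly, which makes cytosolic acetyl-CoA, fell by 1.56 ± 0.03 from 5261 ± 121 to 1772 ± 15.0. Fatty acid oxidation had 3 rises and 4 falls of 16 (adjusted p = 0.815), and Hadh, which also limits insulin release, fell by 2.30 ± 0.06.

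Endoplasmic reticulum stress genes fell on MG-U74A, 20 of 25 with 2 that rose, and 21 and 2 adjusted over the list alone. Their median was -0.82 (adjusted p = 2.54e-04, and adjusted p = 0.303 with an estimated correlation). Ero1b, the oxidase of secretory cells, fell by 1.87 ± 0.03, and Dnajc3 (-1.60 ± 0.08) and Herpud1 (-1.39 ± 0.05) fell as well. The 2 that rose were disulfide isomerase genes, Pdia6 by 2.18 ± 0.05, on a probe set opposed by another of the same gene, and Pdia4 by 1.04 ± 0.05. Ribosomal protein genes rose in 16 of 23 cases with 0 that fell, and 18 and 1 adjusted over the list alone, with a median of 0.48. Among them Rpl10a rose by 1.54 ± 0.04 and Rps3 by 1.52 ± 0.04. The probe set with the highest mean stands for Rps29 there, and the one that fell is left out. Rpl19 also had probe sets that changed in opposite directions. Camera gave adjusted p = 5.17e-07 for the list, and adjusted p = 0.489 with an estimated correlation. That estimate was 0.609, far above the preset of 0.01. Cell cycle genes rose in 14 of 24 cases and fell in 3, with the same counts adjusted over the list alone and a median of 0.65 (adjusted p = 0.00152, and adjusted p = 0.297 with an estimated correlation). The replication gene Mcm4 rose by 2.85 ± 0.23 and the mitotic kinase gene Cdk1, listed below 0 in wild type, by 3.31 ± 0.20, while Plk1 fell by 1.08 ± 0.25. The same arrays had the lower Gapdh ratio and higher lymphocyte, macrophage and fibroblast transcripts, so none of these changes is placed within islet cells.

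The remaining lists on MG-U74A did not pass camera. In the lists that did not pass, the counts adjusted over the list alone were the same, except for 13 falls in oxidative phosphorylation, 6 in liver-type genes, 8 in immediate early genes and 7 in fatty acid synthesis. Liver-type secreted and metabolic genes split 5 to 5 of 16 (adjusted p = 0.640), where Apoa4, listed below 0 in wild type, rose by 4.38 ± 0.16 and Fgg fell by 2.44 ± 0.50. Growth factor and insulin signalling had 3 rises and 5 falls of 18 (adjusted p = 0.841), where Igf1r (-2.40 ± 0.05) and Ghr (-1.79 ± 0.20) fell. Brush border and solute transport had 1 rise and 3 falls of 8 (adjusted p = 0.832), where Slc7a8 fell by 1.53 ± 0.13. Cell cycle inhibitors and apoptosis had 5 rises and 6 falls of 20 (adjusted p = 0.753), and Gadd45a fell by 1.17 ± 0.07. Immediate early and heat shock genes had 9 rises and 7 falls of 27 (adjusted p = 0.832), and Ier3 rose by 2.10 ± 0.04. Of the 30 lists tested, 14 passed, 10 up and 4 down, and 25 passed fry, which asks only whether a list's genes moved one way. With an estimated correlation 0 passed camera, and these 14 had an adjusted p between 0.247 and 0.489.

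On MG-U74B, which carries mostly other genes, the largest rise among genes named by the rule was that of Mzb1 and the largest fall that of Scnn1b. Mzb1 was listed below 0 in wild type and Scnn1b in knockout, so these ranks depend on the constant added. Of 4 tested genes of brush border and solute transport, too few for camera, Cltrn fell, Cdh17 rose by 1.52 ± 0.15 and 2 did not pass the threshold, with the same counts adjusted over the list alone. Cltrn, which encodes collectrin, a membrane protein of beta cells, fell by 4.02 ± 0.11, from 8891 ± 582 to 523 ± 39.6 (SD, n = 2, adjusted p = 0.00204). The directions of Cltrn and Cdh17 are not independent evidence, since earlier work was known when these genes were chosen. Mzb1, a gene of antibody-secreting B cells, rose by 7.32 ± 0.21 from a level listed below 0 to 3985 ± 212 (adjusted p = 0.00204). Of the 7861 tested probe sets 1372 (17.5%) changed, 675 up and 697 down, a balance that was not stable. It was 129 up and 410 down without knockout replicate 1, 288 and 646 without knockout replicate 2, 1176 and 1022 at an adjusted p under 0.10, and 940 and 879 adjusted over both array types. In the full comparison 452 rose and 512 fell by at least 2-fold. Groups did not overlap for 5110 probe sets (65.0%), where chance gives 33.3%. The number called was 1 without wild type replicate 1, 1 without wild type replicate 2, 539 without knockout replicate 1, 764 with no filter and 638 with no variance trend. The median standard error was 0.30 on MG-U74B and 0.13 on MG-U74A, and 7 of 92 genes (7.61%) with at least 2 changed probe sets on MG-U74B had opposite calls.

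Besides Mzb1, the 5 largest rises on MG-U74B were Tbc1d10c (5.19 ± 0.35) and Myo1g (4.95 ± 0.74), both expressed in blood cells, Pcdh9 (4.84 ± 0.47) and Fam3a (4.76 ± 0.53). Tbc1d10c and Fam3a were listed below 0 on both wild type arrays, and Myo1g and Pcdh9 on 1 of them. The sizes of these rises therefore depend on the constant added, and the wild type pair of Tbc1d10c and of Fam3a has no spread. The 5 largest falls were Scnn1b, a sodium channel subunit (-5.82 ± 0.30), Ptprn2, a protein of the secretory granule (-5.35 ± 0.77), Med25 (-5.23 ± 0.34), Lmtk2 (-5.01 ± 0.39) and Scrn1 (-4.78 ± 0.38). Ptprn2 went from 5696 ± 23.6 to 166 ± 183 (adjusted p = 0.0167), and Scnn1b, Med25, Lmtk2 and Scrn1 were listed below 0 in knockout. On MG-U74A a probe set of Ptprn2, at a mean of 80.7 in wild type and 54.3 in knockout with overlapping groups, did not pass the threshold (adjusted p = 0.361). Fam3a and Scrn1 each had 1 other tested probe set on MG-U74B, which did not pass the threshold. Without wild type replicate 1, and likewise without replicate 2, 9 of these 10 genes lost their call, Mzb1 being the exception.

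Of the 30 lists, 13 had at least 5 tested genes on MG-U74B and 2 passed camera. Of 6 genes kept low in beta cells 4 rose and 0 fell, and 6 rose adjusted over the list alone, with a median of 1.41 (adjusted p = 0.0151, and adjusted p = 0.510 with an estimated correlation), among them Smad3 by 1.90 ± 0.30 and Maf by 1.63 ± 0.21. Of 5 insulin secretion genes 3 fell and 0 rose, also adjusted over the list alone, with a median of -1.61 (adjusted p = 0.0393, and adjusted p = 0.510 with an estimated correlation), namely Ptprn2, Cacna1d (-1.74 ± 0.29) and Rab27a (-1.61 ± 0.14). The insulin secretion call ended with quantile normalization (0.0542), with no filter (0.0714) and without wild type replicate 1 (0.0597), and both calls ended without knockout replicate 2 (0.0624 for each). Fry gave 8 of the 13 lists. These changes stood beside the Gapdh 3' to 5' ratio of 3.10 in wild type and 0.907 in knockout on the same arrays.

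The other 11 lists on MG-U74B did not pass camera. Of 7 fatty acid synthesis genes 3 fell, Mlxipl, a glucose-responsive transcription factor gene (-3.88 ± 0.48), Fasn (-2.73 ± 0.55) and Acss2 (-2.28 ± 0.53) (adjusted p = 0.102). The knockout means of Mlxipl and Fasn were listed below 0, and on MG-U74A Fasn, at -0.53 ± 0.16, did not pass the threshold (adjusted p = 0.0559). Of 7 islet transcription factors Neurod1 fell by 1.94 ± 0.17, with 1 rise and 3 falls adjusted over the list alone (adjusted p = 0.188). Of 6 endoplasmic reticulum stress genes Chac1 (-1.06 ± 0.10), Sdf2l1 (-1.18 ± 0.13) and Hyou1 (-0.87 ± 0.14) fell (adjusted p = 0.0633). Of 12 growth factor and insulin signalling genes Igf1r (-2.26 ± 0.13) and Vegfa (-1.07 ± 0.13) fell (adjusted p = 0.520), and of 5 cell cycle inhibitors and apoptosis genes Pmaip1 and Btg1 rose by 1.88 ± 0.21 and 0.70 ± 0.15 (adjusted p = 0.142). No member passed the threshold in the lists of cholesterol synthesis (adjusted p = 0.596), endothelial cells (0.860), and pyruvate use, oxidative phosphorylation and immediate early genes (0.926 for each). Pyy (peptide YY) was at 30203 ± 1325 and 32482 ± 2618 and did not pass the threshold.

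Of 1074 genes tested on both array types by different probe sets, 561 were called on MG-U74A, 226 on MG-U74B and 143 on both. Of the 143, 120 (83.9%) changed in the same direction and 23 in opposite directions. Unrelated directions would match in 50.3%, which is not the value to expect here without an effect of genotype. The array types carry the same replicate labels, so a difference between the genotypes in sample, batch or RNA quality is shared by both and can give the same direction. Of the 143 genes 49 rose and 71 fell on both. Igf1r (-2.40 ± 0.05 and -2.26 ± 0.13) and Neurod1 (-2.53 ± 0.07 and -1.94 ± 0.17) fell, and the G protein subunit gene Gnb4 rose by 3.06 ± 0.22 and 3.07 ± 0.54. Gng12 (-1.28 ± 0.05 and 3.44 ± 0.62) and Dctn3 (0.36 ± 0.05 and -2.79 ± 0.31) changed in opposite directions. The Spearman correlation of the log2 changes across the 1074 genes was 0.362. These genes were named after their values were seen.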

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

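Every test in this part was chosen after the result it concerns had been seen. The values here come from control probe sets outside the comparison of genes, picked out because every knockout array was at least 2 times every wild type array on both array types, with every array at or above 62.5. Opposite-strand control probe sets were not used here. The standard probe sets of BioB for the 3' end, the 5' end and the middle of that hybridisation control, were 24.2, 17.2 and 22.4 times as bright in knockout as in wild type on MG-U74A. On MG-U74B they were 17.3, 24.2 and 29.7 times as bright. The 5' probe set of Gapdh was 5.16 times as bright in knockout on MG-U74A and 6.48 times on MG-U74B, and its middle probe set 2.93 and 4.27 times. The control probe set for the mouse Fas gene was 2.45 and 2.58 times as bright, at intensities of 84.9 in wild type and 208 in knockout on MG-U74A.

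BioB was far brighter in the knockout arrays. BioB is added to the hybridisation and is not made by the mouse, so no biological explanation was tested. A difference of the whole array in hybridisation, staining or scaling is argued against by BioC, BioDn and Cre, which are added with it and whose largest change was 1.42-fold. A different control mixture or processing batch for the genotypes may account for it and stays open, since BioB was picked for differing on both array types and its 22.7 times on MG-U74B and 20.9 times on MG-U74A decide nothing. The labels give no batch, and one shared by all arrays of a genotype cannot be told apart from the genotype in any comparison of genes.

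Transcripts of lymphocytes were higher in the knockout arrays, with a median of 2.07 over 13 genes. A lower share of islet cells that raised every other cell type alike is argued against by the acinar genes, which fell, so that the lymphocyte and acinar medians lay 4.63 apart on the log2 scale. The standard error set beside it, 0.51, is that of a difference of means over genes. It treats genes of the same arrays as independent and does not measure the spread between islet samples. Carried-over lymph node may be the source, given Glycam1, but 7 tested genes of a lymph node list whose values had not been seen had a median of -0.14 with an SD of 1.55, 3 rising and 1 falling, which does not decide it. In the whole list of 17 genes, 10 were tested on MG-U74A, 5 rose and 1 fell, with Ubd and Tnfsf11 up by 2.99 ± 0.12 and 1.97 ± 0.24, and 9 of the 10 were at or above the filter minimum in wild type too. Immune cells in the knockout islets themselves stay open as a biological explanation, as untested.

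Genes of insulin secretion and islet transcription factors were lower in the knockout arrays. Equal dilution of islet RNA by RNA of other cells was not decided as the whole cause. The log2 changes of 25 such genes were unequal, with an SD 13.3 times their median standard error (0.99 against 0.07). That standard error measures only how well the arrays repeat. Genes that other cells also express, such as Sox4, add to the spread under equal dilution too. So do levels near the constant added, such as that of Slc2a2 (22.3 in knockout). A difference in RNA quality could contribute and cannot be told apart from the genotype. The Gapdh 3' to 5' ratio was 3.38 times as high in wild type on MG-U74A and 3.42 times on MG-U74B. The largest difference between arrays of a genotype was 0.03 on the log2 scale. By this ratio the less complete RNA was that of wild type, in which these genes were higher. On MG-U74A the ratio for actin was only 1.28 times as high in wild type. That for 18S ribosomal RNA was 2.78 times as high in knockout. How RNA quality would act on these genes was not tested. Loss of the targeted gene stays open as a biological explanation, as untested beyond the comparison of genotypes itself.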

How the results depend on the processing

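The alternative that left out immunoglobulin probe sets was chosen after seeing the data. No call of a named gene or a list reversed its direction under any alternative tried, while the balance of rises and falls among changed probe sets turned without either wild type replicate on MG-U74A and, on MG-U74B, at an adjusted p under 0.10 and with adjustment over both array types. On MG-U74A the number of changed probe sets stayed within 1.5 times 3974 in 14 of 16 alternatives, such as 3897 with quantile normalization (3787 of them shared) and 3672 adjusted over both array types. Leaving out 1 replicate gave 2439 to 4209, lowest without either wild type replicate. With replicate number as a block 3628 probe sets changed on MG-U74A and 1207 on MG-U74B, and 14 and 2 lists passed. On MG-U74B 764 changed with no filter, 638 with no variance trend and 2198 at an adjusted p under 0.10, against 1372, and leaving out 1 replicate gave 1 to 934. With 1 array left in a genotype, that array is assumed to vary like those of the other genotype. The cause of these losses was not tested.

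Of the 14 lists past the threshold on MG-U74A, 13 or 14 passed under the alternatives that kept all replicates and the preset correlation, and 12 to 14 with 1 replicate left out. With an estimated correlation 0 lists passed on either array type. On 4 arrays that form of camera has few degrees of freedom, so it cannot decide whether correlation between genes made the calls. On MG-U74B 1 list passed in place of 2 with quantile normalization, 1 with no filter, 1 with the stricter filter, which left 9 lists to test, and 0 to 2 with 1 replicate left out. The blood cell list had too few tested genes without either knockout replicate and with the stricter filter, and the insulin secretion list on MG-U74B without knockout replicate 1 and with the stricter filter. On MG-U74B endoplasmic reticulum stress passed with the mean of all probe sets of a gene (adjusted p = 0.0236) and fatty acid synthesis with no variance trend (0.0397).

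Of the 20 named genes on MG-U74A only H1f2 lost its call where it was tested, in 4 alternatives. Wnt4 was below the filter, and so not tested, with the stricter filter and without either wild type replicate. Fam3a on MG-U74B was likewise not tested without knockout replicate 1. On MG-U74B named genes kept their call in 112 results and lost it in 27, of which 9 fell to each wild type replicate left out. Without the immunoglobulin probe sets 3914 and 1372 probe sets changed and 14 and 2 lists passed. Of the scalings, quantile normalization moved the median log2 change most on MG-U74B, by -0.05, and median scaling most on MG-U74A, by -0.02. Signal over background near the filter minimum of 62.5 was not tested as a limit. In simulated data 1.60% of changes of 1 log2 unit were found on MG-U74B against 41.3% on MG-U74A.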

Other observations

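The gene lists in this part were written, and the genes in it picked, after values had been seen, and no test of a list was made. Of 13 tested clock genes on MG-U74A, 9 fell and 2 rose, with a median log2 change of -0.57. Per2 (-1.85 ± 0.22), Nr1d2 (-1.17 ± 0.09), Dbp (-1.13 ± 0.21) and Clock (-0.85 ± 0.12) fell, while Bhlhe40 and Nfil3 rose by 0.77 ± 0.15 and 0.54 ± 0.09. On MG-U74B 3 of 7 fell and 0 rose, the falls being Clock (-3.53 ± 0.48, to a level listed below 0), Nr1d2 (-1.28 ± 0.12) and Rora (-1.25 ± 0.25), with a median of -0.71. The time of day at which islets were taken is not given in the sources used here. Of 13 tested imprinted genes on MG-U74A 7 fell and 0 rose, with a median of -0.96, and 3 of the 13 are also in the lists fixed earlier. Peg3 fell by 2.60 ± 0.09 from 3824 ± 57.2 to 614 ± 73.5, and Meg3 (-1.78 ± 0.07) and Gnas (-1.01 ± 0.04) fell too. On MG-U74B 1 of 5 fell, Zdbf2 (-3.71 ± 0.52), with a median of -0.63. Meg3 (-0.63 ± 0.25, adjusted p = 0.149) and Gnas (-2.23 ± 0.90, adjusted p = 0.156) did not pass the threshold there. The clock and imprinted genes changed beside the lower Gapdh 3' to 5' ratio of the knockout arrays and, on MG-U74A, higher lymphocyte and fibroblast transcripts.

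Probe sets annotated to immunoglobulin genes on MG-U74A numbered 65, of which 57 rose and 0 fell, and 32 of them rose by at least 8-fold. Cybb, a subunit of the phagocyte oxidase, rose by 1.83 ± 0.14 on MG-U74A and 1.87 ± 0.23 on MG-U74B. Among lymph node genes, the brighter probe set of Madcam1, at 1.61 ± 0.49, did not pass the threshold (adjusted p = 0.0550), while its other probe set rose by 1.91 ± 0.24 (adjusted p = 0.00520), and on MG-U74B the 1 tested gene of that list, Lyve1, was at 0.31 ± 0.58.

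The 3' to 5' ratio of the 18S ribosomal RNA probe sets went the other way from that of Gapdh. It was 0.805 ± 0.0479 in wild type and 2.24 ± 0.415 in knockout on MG-U74A, and 0.929 ± 0.288 and 2.89 ± 0.183 on MG-U74B.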
